A study of Homo sapiens with 18 samples.

How the data were processed

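RNA was sequenced in 18 libraries of human prostate cancer cell lines: C4-2B, 22Rv1 and DU145, each with 3 control and 3 EMD knockdown libraries. EMD encodes emerin, a LEM-domain protein of the inner nuclear membrane that binds lamins and the barrier-to-autointegration factor. C4-2B is a bone-metastatic, castration-resistant derivative of LNCaP; 22Rv1 comes from a relapsed xenograft; DU145 comes from a brain metastasis. Per the labels' protocols, C4-2B and 22Rv1 grew in RPMI-1640 and DU145 in DMEM, siRNA against EMD or a scrambled control was delivered with a cationic lipid reagent, and the transfection mix was removed after 24 hours. The library names of the DU145 knockdown samples carry the prefix shEMD, which is the usual mark of a short hairpin vector and disagrees with that protocol; the labels do not settle which reagent these cells received. The time from transfection to harvest is not given. Total RNA was extracted with a column kit and sequenced by a service company, per the labels' protocols. The libraries are described as triplicates, without saying whether these were separate cultures.

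Each line has its own table and its own batch label, so line, batch, table and, for DU145, medium and possibly reagent coincide, and no fit can tell them apart. Control and knockdown libraries of a line share a table and a batch label. The deposited values are RSEM expected counts per gene, given as whole numbers; per the submitters' processing notes, reads were aligned to GRCh38 with STAR and counted with RSEM 1.3.1, and the rounding step is not recorded. The annotation release is not stated, and neither is the kit's strandedness, so reads of overlapping or antisense genes cannot be told apart, and expectation-maximization counting splits reads between near-identical copies. The DU145 table holds 37378 entries, of which 92 are spike-in sequences and 30 are second copies of genes in the pseudoautosomal region; both were left out, leaving 37256 genes. The 22Rv1 table holds 25716 genes and that of C4-2B 22360 genes, with genes of few reads already absent, so a gene missing from those tables was not tested rather than found to be silent. A symbol was matched to 99.4%, 99.1% and 99.21% of the genes of DU145, 22Rv1 and C4-2B. All 3 tables share 18445 genes. No deposited per-sample column was left unused.

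Library totals ran from 14722733 to 25112148 reads in C4-2B, from 15602874 to 30788078 in 22Rv1 and from 21024352 to 43311727 in DU145. More reads lower the counting error at a given level, to which the spread between replicates adds. The floors given below cover counting error only, because reads without molecular identifiers are not independent molecules. A gene without reads in one arm is given a bound against 3 reads over the 3 libraries of that arm. The fitted fold change of such a gene depends on the prior count and is not a bound.

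Within each line, genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested in edgeR 4.0.16 with the robust quasi-likelihood F test in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all genes tested in that line, with a threshold of 0.05. Every adjusted p of a gene below comes from this edgeR test unless another tool is named. Fold changes are log2 of knockdown over control, standard errors are the fold change over the square root of F, and levels are TMM-scaled CPM over the tested genes, as mean ± SD of 3 libraries. Genes were said to rise, fall or change only when past the threshold.

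A set of 24 gene lists was tested with camera in limma 3.58.1 on voom-weighted log2 CPM with a preset correlation of 0.01, for lists with at least 5 tested members, with adjustment over the lists of a line. The lists were nuclear envelope and lamina, neighbours of EMD on Xq28, prostate luminal identity, prostate basal identity, neuroendocrine, stem-like and plasticity regulators, mesenchymal (EMT), G1/S and DNA replication, G2/M and mitosis, p53 targets, interferon response, ATF4 and unfolded protein response, cholesterol synthesis, SRF and MRTF targets, YAP and TEAD targets, WNT and beta-catenin targets, NF-kB and inflammatory, hypoxia and glycolysis, replication-dependent histones, mitochondrially encoded, ribosomal proteins, fibroblast and endothelial cells, and blood cells; 1 further list and some genes that the rule below names are not reported here. Members overlap between some lists, and the nuclear envelope list includes EMD itself, the knockdown target. Camera compares a list with all other genes, and its preset correlation makes it more permissive than one estimated per list from 6 libraries, so both p-values are given. Beside the count of members past the threshold over all genes, a count was made of those adjusted over the list alone. The difference between lines was tested in edgeR with 1 coefficient per group over all 18 libraries, on genes found in all 3 tables. Genes shared by the lines were counted as the intersection of the within-line tests, beside the number that independent lists would share.

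The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes are EMD; per line the 10 largest rises and the 10 largest falls among genes past the threshold with at least 5 CPM in the higher arm, all 3 knockdown libraries on one side of all 3 control libraries and an ordinary symbol; per line and list up to 4 members with the smallest adjusted p; up to 10 genes per direction shared by the lines; 5 genes per pair of lines with the largest difference; and a fixed set with KLK3, SYP, CHGA, KRT8, KRT5, VIM, SOX2, LMNA, LMNB1 and FLNA.

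The alternatives were RLE size factors, library totals only, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, all 18 libraries in the fit, a 2-fold requirement, each library left out in turn, an estimated correlation and fry for the lists, and, for the differences, the 12 libraries of a pair alone. A correction for regional shifts, which takes the median of each 20 Mb window with at least 20 genes out of the knockdown libraries, was added after the data were seen. The alternatives foreseen for normalized values did not apply, since the tables hold counts.

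Regional shifts were measured as medians over 20 Mb windows of genes at 1 CPM or more in the higher arm, against 1000 shuffles of the genes. Gene positions and gene types came from GENCODE 29 on GRCh38, which may not be the release the submitters used. The tests were tried on simulated counts drawn from the real means and library sizes. In C4-2B, edgeR found 50% of genes changed 1.5-fold and 78% of those changed 2-fold; in 22Rv1 the shares were 69.4% and 81.6%, and in DU145 56.2% and 71.4%. At most 0.107% of unchanged genes were called, and the list that was moved was found in all 3 lines with 0 unmoved lists called by camera. Genes were drawn independently of each other and few were changed. The simulation therefore does not show how often camera calls lists of correlated genes, or where many genes change. For the difference between lines, 54% of 1.5-fold and 80% of 2-fold differences were found for C4-2B against 22Rv1, and 60% and 84% for C4-2B against DU145. Summaries and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.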

Results

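The data are gene-level RNA-seq counts from 18 libraries of prostate cancer cells in 6 groups of 3: control and EMD knockdown cultures of C4-2B, 22Rv1 and DU145. The series asks what loss of emerin, the inner nuclear membrane protein encoded by EMD, does to prostate cancer cells whose nuclei become very small. Summed over genes, the C4-2B libraries hold 15530197, 19385564 and 25112148 reads in controls 1 to 3 and 14722733, 17488863 and 16139701 in knockdowns 1 to 3. In 22Rv1 the control totals were 28538877, 15602874 and 30788078 and the knockdown totals 25441159, 16795129 and 17459508. In DU145 they were 21024352, 43311727 and 34199522 for control and 35456933, 29191847 and 34303306 for knockdown, without the sequences left out. Replicate libraries of a group varied more than counting alone gives (chi-square per degree of freedom 2.31 to 8.40). The tests estimate that extra spread from the replicates.

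EMD fell in all 3 lines, and in each line all 3 knockdown libraries lay below all 3 control libraries. The gene (ENSG00000102119) lies on chromosome X from 154379197 to 154381523 on the plus strand of GRCh38, and its counts cover the whole gene. In C4-2B its level went from 69.9 ± 4.53 to 8.29 ± 1.82 CPM (mean ± SD, n = 3 per arm), a log2 fold change of -3.07 ± 0.11 (SE; edgeR adjusted p = 3.37e-14). In 22Rv1 it went from 65.3 ± 4.38 to 19.5 ± 1.82 CPM (-1.73 ± 0.07, edgeR adjusted p = 4.29e-14). In DU145 it went from 44.5 ± 3.54 to 4.80 ± 0.20 CPM (-3.21 ± 0.08, edgeR adjusted p = 1.67e-22). The knockdown was shallower in 22Rv1. The fold change of C4-2B less that of 22Rv1 was -1.29 ± 0.14 (adjusted p = 9.78e-09). That of 22Rv1 less that of DU145 was 1.42 ± 0.14 (adjusted p = 9.39e-10). C4-2B and DU145 differed by 0.13 ± 0.16 (adjusted p = 0.537).

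**Figure D1:**
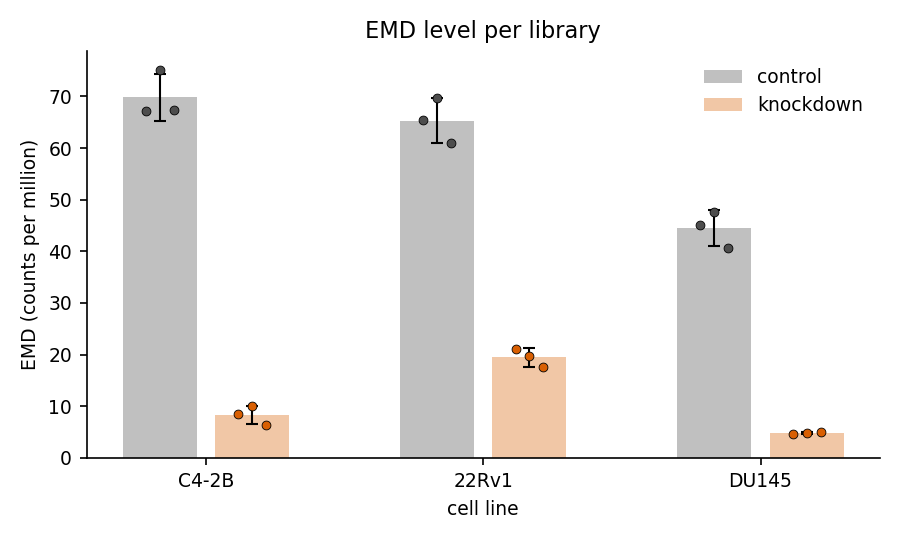
EMD level (CPM) for control (grey) and knockdown (orange) cultures of each line; bars are means, error bars SDs and points the 3 libraries of each group. Mean levels fell from 69.9 to 8.29 in C4-2B, from 65.3 to 19.5 in 22Rv1 and from 44.5 to 4.80 in DU145.

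In C4-2B, genes of DNA replication and mitosis fell together after EMD knockdown while targets of the tumour suppressor p53 rose. All 25 tested genes of the G2/M and mitosis list fell, with a median log2 fold change of -2.30 (camera adjusted p = 1.5e-28, and adjusted p = 0.00712 with an estimated correlation). TOP2A, the topoisomerase that untangles sister chromatids, went from 138 ± 1.7 to 31.6 ± 1.36 CPM (-2.12 ± 0.06). CCNB1, the mitotic cyclin B1, went from 103 ± 6.24 to 24.1 ± 0.45 CPM (-2.10 ± 0.06) and CDK1, its kinase, from 194 ± 8.14 to 72.1 ± 1.24 CPM (-1.43 ± 0.05). HMMR, a spindle-associated hyaluronan receptor, fell by 2.70 ± 0.09 on the log2 scale. Of the 25 genes of G1/S and DNA replication, 24 fell (median -1.09, adjusted p = 3.67e-19, and adjusted p = 0.00712 with an estimated correlation). RRM2, a subunit of the ribonucleotide reductase that makes deoxynucleotides, went from 75.4 ± 4.4 to 12.9 ± 1.4 CPM (-2.54 ± 0.08). MCM2, part of the replicative helicase, went from 109 ± 2.47 to 41.8 ± 3.24 CPM (-1.38 ± 0.06). Of 24 p53 targets, 22 rose and 1 fell (median 0.62, adjusted p = 1.42e-15, and adjusted p = 0.00712 with an estimated correlation). GDF15, a secreted stress cytokine, rose from 620 ± 17.6 to 1665 ± 66.5 CPM (1.42 ± 0.04). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 233 ± 1.91 to 588 ± 14.4 CPM (1.34 ± 0.04).

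Luminal identity genes of C4-2B went both ways, while KLK3, NDRG1 and MAF, which are not on that list, fell. KLK3, which encodes prostate-specific antigen, fell from 1509 ± 11.0 to 951 ± 42.8 CPM (-0.67 ± 0.04). The stress-response gene NDRG1 fell from 382 ± 10.6 to 141 ± 4.82 CPM (-1.43 ± 0.04) and the transcription factor MAF by 1.99 ± 0.06 on the log2 scale. The luminal identity list did not move as a whole (7 rose, 6 fell and 6 did not pass, of 19; median -0.03, adjusted p = 0.957). The tight junction gene CLDN4 rose by 0.81 ± 0.04 and the keratin KRT19 fell by 0.87 ± 0.08. The luminal keratin KRT8 was at 441 ± 7.35 and 431 ± 15.7 CPM (-0.04 ± 0.04, adjusted p = 0.493). Among stem-like and plasticity regulators, 8 of 18 fell and 3 rose (median -0.15, adjusted p = 0.0769). ALDH1A1, a retinaldehyde dehydrogenase (-1.39 ± 0.04), and the progenitor factor SOX9 (-1.47 ± 0.09) were among the falls. Of 8 neuroendocrine genes tested, 3 fell and 0 rose (median -0.44, adjusted p = 0.102). STMN1 (-1.64 ± 0.06) and AURKA (-1.91 ± 0.10), which fell most clearly, also serve mitosis. The lowest log2 fold change of the list, -3.56, was that of another gene. SYP gave -0.52 ± 0.34 (adjusted p = 0.23) and VIM -0.44 ± 0.18 (adjusted p = 0.0588). VIM passed without control 1 (adjusted p = 0.0268), and VIM (0.0181) and SYP (0.0357) passed in the fit of all 18 libraries. CHGA, KRT5 and SOX2 are not in this table.

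At the nuclear envelope of C4-2B, 10 of 25 genes fell (11 adjusted over the list alone) and 5 rose, with a median of -0.08 (adjusted p = 0.0482, and adjusted p = 0.421 with an estimated correlation). EMD, the knockdown target, is a member and is among the falls, and the list was not tested without it. LMNB1, which encodes lamin B1, went from 99.7 ± 2.17 to 38.8 ± 5.04 CPM (-1.36 ± 0.07). TMPO, which encodes the LEM-domain protein LAP2, went from 179 ± 6.92 to 96.8 ± 0.64 CPM (-0.89 ± 0.04) and the torsin cofactor TOR1AIP1 fell by 0.50 ± 0.05. LMNA, which encodes lamins A and C, rose by 0.13 ± 0.05 (adjusted p = 0.0392), with overlapping libraries. It did not pass without control 1, control 2, knockdown 1 or knockdown 3 (adjusted p between 0.0662 and 0.278). The call of the list was lost with library totals in place of TMM (adjusted p = 0.0871), without control 2 (0.0612) and without knockdown 2 (0.0657). Over its 11 alternatives the adjusted p ran from 0.00116 with fry, which does not compare a list with other genes, to 0.421 with the estimated correlation.

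Ribosomal protein genes of C4-2B rose in 31 of 43 cases (32 adjusted over the list alone; median 0.22, adjusted p = 1.79e-12, and adjusted p = 0.421 with an estimated correlation). RPS6 rose by 0.42 ± 0.04 and RPL13 by 0.40 ± 0.04. Of the 13 mitochondrially encoded genes 7 fell (9 adjusted over the list alone) and 1 rose (median -0.43, adjusted p = 4.51e-05, and adjusted p = 0.425 with an estimated correlation). MT-CO1 fell by 0.48 ± 0.04. The mitochondrial share of reads went from between 5.91% and 6.38% in the controls to between 4.27% and 4.89%. Hypoxia and glycolysis genes fell in 11 of 23 cases and rose in 2 (median -0.29, adjusted p = 0.0017, and adjusted p = 0.293 with an estimated correlation). The glycolytic enzymes LDHA (-0.68 ± 0.04) and GAPDH (-0.55 ± 0.04) were among the falls. Cholesterol synthesis genes fell in 10 of 25 cases and rose in 5 (median -0.13, adjusted p = 0.0227, and adjusted p = 0.302 with an estimated correlation). HMGCS1 (-0.73 ± 0.05) and FDPS (-0.63 ± 0.04) of the mevalonate pathway fell. No shift was detected for the histones (median 0.10, adjusted p = 0.328) or the ATF4 and unfolded protein response (-0.15, 0.505). The same held for the interferon response (-0.12, 0.531), where 3 rose and 3 fell, or 1 and 2 adjusted over the list alone. It also held for YAP and TEAD targets (0.01, 0.531), WNT targets (0.11, 0.615), SRF and MRTF targets (0.07, 0.756) and basal identity (-0.34, 0.957). The mesenchymal list (0.02, 0.585; 4 fell, 5 adjusted over the list alone), NF-kB (-0.06, 0.801; 4 fell, 5 adjusted over the list alone) and the Xq28 neighbours of EMD (-0.02, 0.957; 6 fell, 7 adjusted over the list alone) did not pass either. In the other lists named here the count adjusted over the list alone was the same as over all genes. Of the markers of other cell types too few were tested for a list test. They were 3 of fibroblasts and endothelium, of which VWF fell (-0.66 ± 0.10), and 2 of blood cells, of which LYZ fell (-2.86 ± 0.52) from 1.99 ± 0.92 CPM.

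Across the C4-2B transcriptome, 6584 of 15801 tested genes changed, 3068 up and 3516 down. Of these, 459 rose and 588 fell by at least 2-fold. Among the largest rises were those of HSPA6, a heat-inducible HSP70 (4.88 ± 0.36, from 0.18 to 5.64 CPM), the lysosomal membrane protein LAMP3 (2.97 ± 0.17) and the collagen chaperone SERPINH1 (2.88 ± 0.26). The MAP kinase phosphatase DUSP4 went from 15.9 ± 1.35 to 92.8 ± 5.43 CPM (2.54 ± 0.07). Among the largest falls were those of the natriuretic peptide receptor NPR3 (-5.09 ± 0.36), the metalloreductase STEAP4 (-4.03 ± 0.26) and the transcription factor RUNX1 (-3.41 ± 0.29). IGFBP3, a binding protein of insulin-like growth factors, went from 301 ± 1.86 to 35.2 ± 1.33 CPM (-3.09 ± 0.05). The kinetochore gene SPC25 (-2.82 ± 0.21) and the helicase PIF1 (-2.77 ± 0.20) were also among the 10 largest. Of 122 named genes that changed in C4-2B, 120 had all 3 knockdown libraries on one side of all 3 control libraries, and IRF9 and LMNA did not. The naming rule requires this of the largest changes and favours it for list members, so these counts show no more than the direction of the named genes. With library totals in place of TMM, 3871 genes rose and 2922 fell, which moves the share of rises from 46.6% to 57.0%. For each of the 9 lists past the threshold, the knockdown libraries all lay on one side of the controls in mean log2 level. They did so for most of the other lists too, luminal identity included, so this gives the 9 lists no support. For each of the 9, the estimated correlation gave the highest adjusted p of the 11 alternatives.

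In 22Rv1 the direction of the cell cycle genes was the opposite. Replication and mitosis genes rose after EMD knockdown, while most genes of the mesenchymal, hypoxia and basal lists fell. Of 25 genes of G1/S and DNA replication 22 rose and 1 fell (median 0.42, adjusted p = 3.78e-07, and adjusted p = 0.0766 with an estimated correlation). UHRF1, which guides maintenance DNA methylation, went from 60.7 ± 1.24 to 142 ± 3.51 CPM (1.23 ± 0.04). MCM5 rose by 0.94 ± 0.04 and the replication clamp PCNA by 0.76 ± 0.03. Of 25 genes of G2/M and mitosis 21 rose and 1 fell (median 0.47, adjusted p = 3.78e-07, and adjusted p = 0.153 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, went from 106 ± 3.37 to 229 ± 5.13 CPM (1.11 ± 0.04). CCNB1 rose by 0.98 ± 0.04 and the mitotic kinase PLK1 by 1.00 ± 0.05. Among p53 targets 16 of 25 fell and 6 rose (median -0.37, adjusted p = 0.0118, and adjusted p = 0.187 with an estimated correlation). CDKN1A went from 283 ± 10.4 to 156 ± 2.61 CPM (-0.86 ± 0.04) and the death receptor TNFRSF10B fell by 2.02 ± 0.04 on the log2 scale.

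Genes of low expression fell together in 22Rv1, with medians of -0.44 at 0.5 to 2 CPM and -0.33 at 2 to 10 CPM, where 31.7% and 27.4% of genes fell by at least 2-fold. That shift stands beside the mesenchymal, basal and NF-kB lists below. Medians were 0.134 at 30 to 100 CPM and 0.146 from 100 CPM, which stands beside the lists that rose in this line. The part of these shifts in the list calls was not tested. Of 15 tested mesenchymal genes 12 fell and 1 rose (median -1.54, adjusted p = 0.00188, and adjusted p = 0.193 with an estimated correlation). FN1, which encodes fibronectin, went from 548 ± 28.8 to 54.8 ± 2.34 CPM (-3.32 ± 0.05). The fibronectin receptor subunit ITGA5 (-2.07 ± 0.08), the tenascin gene TNC (-1.54 ± 0.08) and the collagen gene COL1A1 (-1.87 ± 0.12) also fell. Of 12 basal identity genes 9 fell and 1 rose (median -1.02, adjusted p = 0.0223, and adjusted p = 0.187 with an estimated correlation). The nerve growth factor receptor NGFR went from 33.4 ± 1.7 to 2.96 ± 0.58 CPM (-3.49 ± 0.12). SRF and MRTF targets fell in 15 of 24 cases and rose in 5 (median -0.55, adjusted p = 0.0157, and adjusted p = 0.193 with an estimated correlation). SRF, the serum response factor itself, went from 494 ± 16.0 to 149.7 ± 4.29 CPM (-1.72 ± 0.04) and the myosin light chain MYL9 fell by 1.75 ± 0.11. Hypoxia and glycolysis genes fell in 18 of 24 cases and rose in 4 (median -0.62, adjusted p = 0.00045, and adjusted p = 0.138 with an estimated correlation). The angiogenic factor VEGFA went from 271 ± 16.6 to 51.8 ± 3.21 CPM (-2.39 ± 0.05). NF-kB and inflammatory genes fell in 11 of 15 cases and rose in 1 (median -0.97, adjusted p = 0.00842, and adjusted p = 0.156 with an estimated correlation). The inhibitor NFKBIA fell by 0.96 ± 0.04.

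In 22Rv1 the serine protease gene TMPRSS2 went from 97.8 ± 3.54 to 14.7 ± 0.57 CPM (-2.73 ± 0.06) and FKBP5, a chaperone of steroid receptors, from 321 ± 11.5 to 162 ± 3.76 CPM (-0.99 ± 0.04). KLK3 gave -0.17 ± 0.09 (adjusted p = 0.0879). KRT8 fell from 889 ± 43.8 to 558 ± 9.44 CPM (-0.67 ± 0.04), while SPDEF, a luminal transcription factor, rose by 1.38 ± 0.05. The luminal list as a whole did not pass (10 fell and 7 rose of 19; median -0.21, adjusted p = 0.262). Neuroendocrine genes went both ways and the list did not pass (14 fell and 7 rose of 24; median -0.77, adjusted p = 0.0828). CHGA, which encodes chromogranin A, rose from 47.1 ± 1.19 to 105 ± 3.31 CPM (1.16 ± 0.05) and the synaptic vesicle gene SYP by 0.27 ± 0.05. In contrast, the neuronal RNA-binding protein ELAVL3 fell by 4.46 ± 0.10, the Notch ligand DLL3 by 3.34 ± 0.13 and the neuron-specific enolase ENO2 from 334 ± 6.09 to 109 ± 2.24 CPM (-1.61 ± 0.04). Stem-like and plasticity regulators rose in 11 of 23 cases and fell in 5 (median 0.23, adjusted p = 0.12). The intestinal stem cell receptor LGR5 rose by 2.91 ± 0.15 and the histone methyltransferase EZH2 by 1.01 ± 0.07, and the receptor kinase KIT fell by 4.71 ± 0.31. VIM gave 0.58 ± 0.31 (adjusted p = 0.11) and SOX2 0.55 ± 0.35 (adjusted p = 0.173). KRT5 held 2 reads in the controls and 0 in the knockdown.

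Nuclear envelope genes of 22Rv1 rose in 13 of 25 cases and fell in 5, EMD among them (median 0.26, adjusted p = 0.0171, and adjusted p = 0.193 with an estimated correlation). LMNB1 rose from 179.8 ± 5.03 to 258 ± 5.95 CPM (0.53 ± 0.04) and the lamin A protease ZMPSTE24 by 1.06 ± 0.05. BCLAF1, an emerin-binding transcription regulator, rose by 1.31 ± 0.04 and CTNNB1, which encodes beta-catenin, by 0.66 ± 0.03. LMNA gave 0.06 ± 0.04 (adjusted p = 0.167). The Xq28 neighbours of EMD rose in 12 of 19 cases and fell in 2 (median 0.27, adjusted p = 0.0118, and adjusted p = 0.193 with an estimated correlation). That call ended when window medians were removed (adjusted p = 0.0561). Its range over 11 alternatives was 0.000236 with fry, which does not compare a list with other genes, to 0.193 with the estimated correlation. Mitochondrially encoded genes rose in 11 of 13 cases (median 0.55, adjusted p = 0.000101, and adjusted p = 0.247 with an estimated correlation). MT-CO3 rose by 1.06 ± 0.04 and the mitochondrial share of reads went from between 0.96% and 1.2% to between 1.45% and 1.54%. Cholesterol synthesis genes rose in 15 of 25 cases and fell in 4 (median 0.28, adjusted p = 0.00756, and adjusted p = 0.153 with an estimated correlation). ACAT2 rose by 1.08 ± 0.05 and DHCR7 by 0.69 ± 0.04. Ribosomal protein genes fell in 29 of 43 cases and rose in 2 (median -0.15, adjusted p = 2.59e-05, and adjusted p = 0.361 with an estimated correlation). RPL13A fell by 0.50 ± 0.03. The ATF4 and unfolded protein response list split (13 fell and 11 rose of 25; median -0.30, adjusted p = 0.32). The mTOR inhibitor DDIT4 went from 312 ± 7.11 to 28.5 ± 1.8 CPM (-3.45 ± 0.05), while the endoplasmic reticulum chaperone HSPA5 rose by 0.82 ± 0.03.

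The remaining lists of 22Rv1 did not pass. They were YAP and TEAD targets (median -0.17, adjusted p = 0.065), histones (0.74, 0.107), interferon response (-0.61, 0.12) and WNT targets (-0.26, 0.232). Of 16 interferon genes 8 fell, or 9 adjusted over the list alone, and 3 rose. For every other list the count adjusted over the list alone was the same. Of the other cell types' markers, 2 of fibroblasts and endothelium were tested, of which ESAM fell (-1.86 ± 0.17). Of 4 blood cell genes, ITGAM went from 1.03 ± 0.36 CPM to 0 reads. HBA1 and HBA2, near-identical copies whose reads cannot be told apart with certainty, moved in opposite directions. In all, 11288 of 16656 tested genes changed, 5583 up and 5705 down. Library totals in place of TMM gave 4709 rises and 6492 falls, moving the share of rises from 49.5% to 42%. At 2-fold or more there were 2455 falls and 610 rises. Among the largest rises were those of the interferon-induced GTPase MX2 (3.67 ± 0.23) and UGT2B15, which glucuronidates androgens (2.67 ± 0.07). KLF2, a Krüppel-like factor, went from 16.2 ± 2.07 to 128 ± 1.78 CPM (2.99 ± 0.07) and the tetraspanin TSPAN8 from 9.51 ± 1.04 to 63.4 ± 1.98 CPM (2.73 ± 0.08). Among the falls, TMEM265 went from 18.5 ± 0.99 CPM to 0 reads, at least 357-fold lower, and the sodium channel subunit SCN4B from 5.99 ± 0.6 CPM to 0 reads, at least 115-fold lower. IGFBP5 went from 139 ± 4.33 to 0.72 ± 0.29 CPM (-7.57 ± 0.11). All 130 named genes that changed in 22Rv1 had every knockdown library on one side of every control library, which the naming rule favours. The same held for the mean level of every list, passing or not, so it gives no support to the 14 lists past the threshold. The estimated correlation gave each of the 14 its highest adjusted p of 11 alternatives. Leaving out 1 library changed some calls. KLK3 passed without control 1 (adjusted p = 0.0246), VIM without control 2 (0.022), and SOX2 without knockdown 2 (0.0201). KLK3 also passed with library totals in place of TMM (0.0157), VIM with limma-voom (0.0438), and both in the fit of all 18 libraries (0.034 and 0.0207). YAP and TEAD targets passed without control 3 (0.0307) or knockdown 3 (0.0436) and histones without knockdown 2 (0.0356) or 3 (0.0409). With all libraries these 2 lists gave adjusted p = 0.405 and 0.384 with an estimated correlation.

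In DU145, SRF and MRTF targets and genes of luminal and basal identity and of cholesterol synthesis fell more often than they rose. Hypoxia genes rose more often than they fell, and the cell cycle lists did not pass. Of 22 SRF and MRTF targets 14 fell and 3 rose (median -0.38, adjusted p = 6.96e-05, and adjusted p = 0.426 with an estimated correlation). The smooth muscle protein gene TAGLN went from 78.4 ± 3.2 to 2.36 ± 0.18 CPM (-5.06 ± 0.08) and MYL9 from 193 ± 6.28 to 41.6 ± 1.04 CPM (-2.22 ± 0.05). FLNA, which encodes the actin crosslinker filamin A and lies 4.6 kb from EMD, went from 2046 ± 140.1 to 863 ± 22.9 CPM (-1.246 ± 0.053). Luminal identity genes fell in 9 of 18 cases (10 adjusted over the list alone) and rose in 6 (median -0.53, adjusted p = 0.0492, and adjusted p = 0.426 with an estimated correlation). KRT8 went from 1243 ± 49.0 to 403 ± 21.6 CPM (-1.62 ± 0.05). The surface glycoprotein CD24 went from 134 ± 3.59 to 8.97 ± 0.19 CPM (-3.91 ± 0.06). CDH1, which encodes E-cadherin, went from 22.6 ± 0.51 to 5.04 ± 0.49 CPM (-2.17 ± 0.08). Basal identity genes fell in 9 of 14 cases and rose in 3 (median -0.33, adjusted p = 0.0242, and adjusted p = 0.426 with an estimated correlation). The hemidesmosome genes ITGB4 (-3.89 ± 0.07) and COL17A1 (-1.99 ± 0.09) fell. Mesenchymal genes fell in 10 of 21 cases (11 adjusted over the list alone) and rose in 5 (median -0.35, adjusted p = 0.0243, and adjusted p = 0.426 with an estimated correlation). The collagen crosslinking enzyme LOX fell by 3.35 ± 0.08 and FN1 by 1.83 ± 0.08, while VIM was at 2000 ± 45.0 and 1942 ± 96.1 CPM (-0.04 ± 0.05, adjusted p = 0.533).

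Cholesterol synthesis genes of DU145 fell in 19 of 25 cases and rose in 3 (median -0.37, adjusted p = 1.33e-05, and adjusted p = 0.426 with an estimated correlation). CYP51A1 (-0.96 ± 0.05) and HMGCS1 (-0.77 ± 0.05) were among them. Hypoxia and glycolysis genes rose in 14 of 24 cases and fell in 2 (median 0.24, adjusted p = 0.00339, and adjusted p = 0.479 with an estimated correlation). The vasodilator peptide ADM went from 3.86 ± 0.48 to 48.4 ± 1.35 CPM (3.67 ± 0.08) and LDHA from 756 ± 13.0 to 1303 ± 53.6 CPM (0.79 ± 0.05). ATF4 and unfolded protein response genes rose in 12 of 25 cases and fell in 5 (median 0.16, adjusted p = 0.0492, and adjusted p = 0.781 with an estimated correlation). DDIT4 rose by 1.13 ± 0.06 and the cystine transporter SLC7A11 by 1.09 ± 0.05. NF-kB and inflammatory genes fell in 11 of 21 cases (12 adjusted over the list alone) and rose in 5 (median -0.36, adjusted p = 0.048, and adjusted p = 0.638 with an estimated correlation). The chemokine CXCL8 fell by 2.85 ± 0.07 and the feedback inhibitor TNFAIP3 by 2.97 ± 0.07, while BIRC3 rose by 1.24 ± 0.05. Interferon response genes fell in 11 of 22 cases (12 adjusted over the list alone) and rose in 2 (median -0.43, adjusted p = 0.0373, and adjusted p = 0.426 with an estimated correlation). OAS3 (-1.29 ± 0.06) and IFIT3 (-2.28 ± 0.14) were among the falls. All 13 mitochondrially encoded genes fell (median -0.37, adjusted p = 7.01e-07, and adjusted p = 0.426 with an estimated correlation). The mitochondrial share of reads went from between 8.94% and 9.12% to between 7.11% and 7.35%. Ribosomal protein genes rose in 37 of 43 cases and fell in 3 (median 0.28, adjusted p = 9.32e-09, and adjusted p = 0.553 with an estimated correlation). RPL13A rose by 0.46 ± 0.05.

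Cell cycle genes of DU145 moved little. Of 25 genes of G2/M and mitosis 14 rose and 5 fell (median 0.13, adjusted p = 0.0638), with CDC20 up by 0.55 ± 0.05 and NUSAP1 down by 0.78 ± 0.05. Of 25 genes of G1/S 6 rose and 6 fell (median -0.05, adjusted p = 0.705). Of 23 p53 targets 11 fell (12 adjusted over the list alone) and 5 rose (median -0.14, adjusted p = 0.0674). CDKN1A went from 64.7 ± 4.86 to 24.0 ± 2.02 CPM (-1.44 ± 0.07). Nuclear envelope genes split evenly, 9 rising (10 adjusted over the list alone) and 9 falling of 25, the target EMD among the falls (median 0.06, adjusted p = 0.926). The giant nesprin SYNE1 rose from 64.4 ± 6.07 to 207 ± 16.9 CPM (1.68 ± 0.07). SYNE3 fell by 2.37 ± 0.12 and SUN2, the LINC complex protein that binds nesprins, by 0.54 ± 0.06. LMNB1 rose by 0.23 ± 0.05 and LMNA fell by 0.18 ± 0.05. Neuroendocrine genes rose in 7 of 20 cases and fell in 1 (median 0.26, adjusted p = 0.0651). Of 23 stem-like regulators 6 rose (7 adjusted over the list alone) and 6 fell (median 0.06, adjusted p = 0.705). KLF4 (1.57 ± 0.08) and NES (1.16 ± 0.07) rose and SOX9 (-1.10 ± 0.08) fell. KLK3 was at 0.53 ± 0.20 CPM in the controls. SYP gave 0.43 ± 0.29 (adjusted p = 0.247) and SOX2 0.30 ± 0.43 (adjusted p = 0.616). CHGA held 9 reads in the controls and 4 in the knockdown, and KRT5 0 and 1. Of the others, YAP and TEAD targets (median -0.13, adjusted p = 0.0638), histones (0.73, 0.0641; 8 rose, 9 adjusted over the list alone), and blood cell markers (-0.32, 0.572) did not pass. Nor did the Xq28 neighbours (-0.06, 0.956; 8 rose, 9 adjusted over the list alone), fibroblast and endothelial markers (-0.08, 0.956) and WNT targets (0.07, 0.974). Counts adjusted over the list alone were equal in the lists given without one.

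In DU145, 9232 of 19377 tested genes changed, 4664 up and 4568 down. Of these, 716 rose and 876 fell by at least 2-fold. With library totals in place of TMM, 5555 rose and 4176 fell, which moves the share of rises from 50.5% to 57.1%. The largest rises included the long non-coding RNA UCA1, from 0.14 ± 0.06 to 16.8 ± 0.28 CPM (7.04 ± 0.17). The basement membrane collagen COL4A5 (5.64 ± 0.14) and the guidance receptor ROBO1 (5.03 ± 0.24) also rose. TKTL1, a transketolase-like gene 48.8 kb from EMD, went from 0.18 ± 0.08 to 14.3 ± 1.55 CPM (6.39 ± 0.19). Among the falls, BCHE, which encodes butyrylcholinesterase, went from 91.8 ± 2.01 CPM to 0 reads, at least 3081-fold lower. CAVIN2, a coat protein of caveolae, went from 159 ± 4.89 to 4.53 ± 0.24 CPM (-5.13 ± 0.07) and the vitamin D hydroxylase CYP24A1 from 89.3 ± 0.90 to 2.56 ± 0.23 CPM (-5.12 ± 0.07). The protease inhibitor SERPINA1 went from 20.5 ± 1.03 to 0.29 ± 0.04 CPM (-6.14 ± 0.14). All 126 named genes that changed in DU145 had every knockdown library on one side of every control library, which the naming rule favours. The same held for the mean level of each of the 11 lists past the threshold, but also of most lists that did not pass, so it gives the 11 no support. For each of the 11 lists the estimated correlation gave the highest adjusted p of 11 alternatives.

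Whole stretches of the DU145 genome also moved. In 13 of 154 windows of 20 Mb the median log2 fold change differed from the genome median by more than in any of 1000 shuffles, 10 lower and 3 higher, by 0.49 to 0.62. Of the genes inside these windows 61.2% changed (786 of 1284), against 46.7% outside (8446 of 18093). The windows were picked by their median change, so a higher share inside follows in part from that choice. The basal and mesenchymal calls ended once window medians were removed (adjusted p = 0.0627 for both). Over 11 alternatives they ranged from 0.000193 and 5.18e-05 with fry, which does not compare a list with other genes, to 0.426 with the estimated correlation. The G2/M and mitosis (adjusted p = 0.00023), YAP and TEAD (0.00815), p53 (0.0298) and neuroendocrine (0.035) lists then passed. Without the correction, these 4 lists gave adjusted p = 0.781, 0.699, 0.699 and 0.426 with an estimated correlation. Single libraries also decided calls. That of ATF4 ended without control 1 (adjusted p = 0.0608), control 3 (0.0543) or knockdown 2 (0.0853), and that of NF-kB without control 2 (0.0741) or knockdown 3 (0.0889). LMNA did not pass without knockdown 1 (0.106). G2/M and mitosis passed with library totals in place of TMM (0.0233), and without control 2 (0.0234), control 3 (0.0443), knockdown 1 (0.0266) or knockdown 3 (0.0192). YAP and TEAD targets passed without control 1 (0.0371) or knockdown 2 (0.0301) and histones without control 1 (0.0421) or knockdown 2 (0.0335). With all libraries, histones gave adjusted p = 0.455 with an estimated correlation. The p53 and neuroendocrine lists passed without knockdown 2 (0.0454 each).

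**Figure D2:**
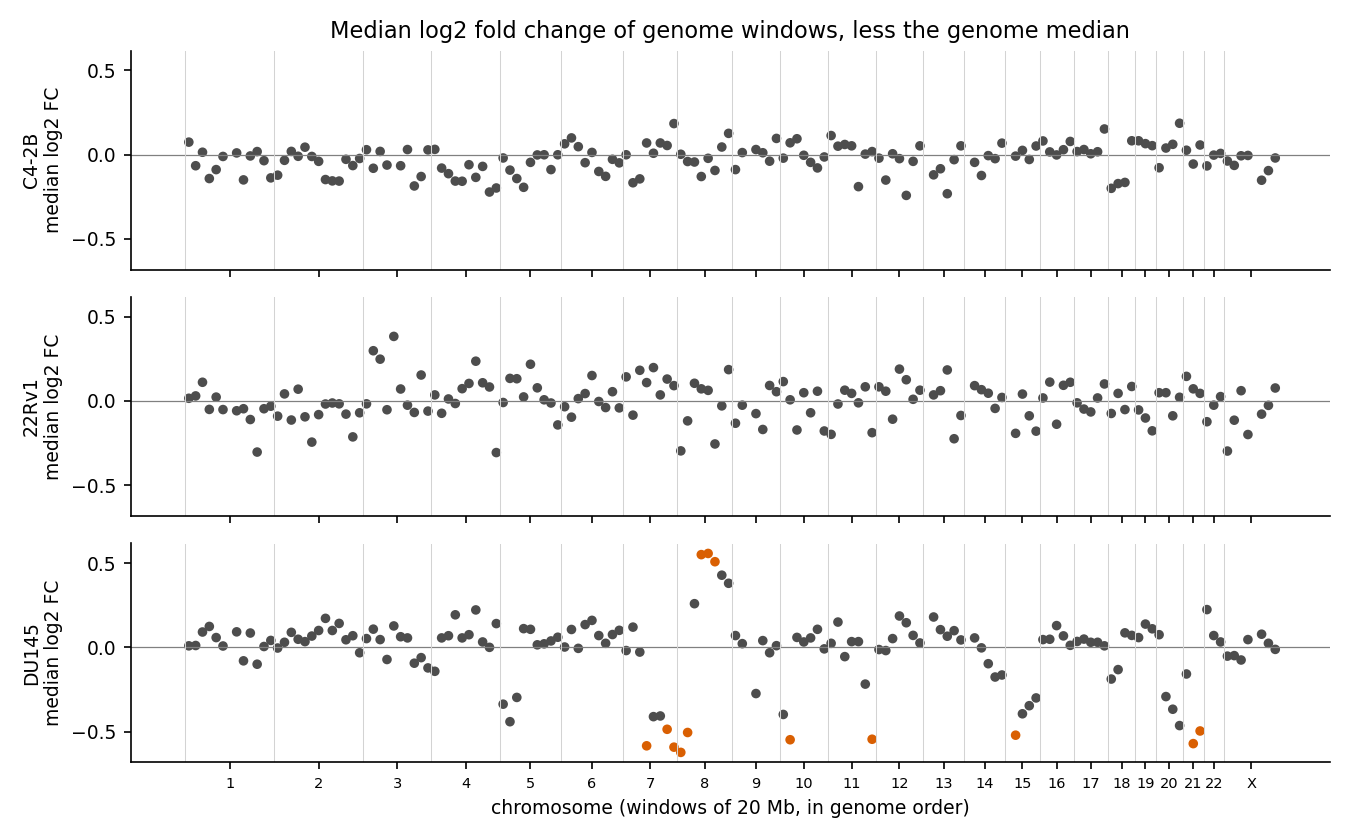
Median log2 fold change, knockdown over control, of genes in 20 Mb windows along the genome, less the genome median, for each line; orange points lie beyond all 1000 shuffles of the genes. DU145 has 13 such windows, on chromosomes 7, 8, 10, 11, 15 and 21, and the same windows reach at most 0.18 in C4-2B and 0.30 in 22Rv1.

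EMD fell in all 3 lines, but across genes the responses of the lines were almost uncorrelated. Across 13078 genes tested in all lines, the Pearson correlation of log2 fold changes was -0.09 between C4-2B and 22Rv1, -0.01 between C4-2B and DU145 and 0.02 between 22Rv1 and DU145. These are correlations across genes, which are not independent replicates. Some lists passed in the same direction in a pair of lines. The basal, mesenchymal, SRF and MRTF, and NF-kB lists fell in 22Rv1 and DU145. The mitochondrially encoded and cholesterol lists fell, and the ribosomal list rose, in C4-2B and DU145. Hypoxia genes fell in C4-2B and 22Rv1. With an estimated correlation none of these passed in both lines. Other lists passed in opposite directions, such as G2/M and mitosis in C4-2B and 22Rv1. Past the threshold in the same direction in all 3 lines were 580 genes, 277 up and 303 down, where independent lists would share 319.1 and 290.2. Among the shared rises were SQSTM1, which encodes the autophagy receptor p62 (0.80 ± 0.04 in C4-2B, 0.67 ± 0.04 in 22Rv1 and 0.83 ± 0.05 in DU145), and the adenosine receptor ADORA2A (0.98 ± 0.19, 1.16 ± 0.09 and 0.89 ± 0.10). Among the shared falls were the antiviral synthetase OAS3 (-1.45 ± 0.11, -1.86 ± 0.08 and -1.29 ± 0.06), the kinase anchor AKAP12 (-1.42 ± 0.30, -2.02 ± 0.05 and -1.98 ± 0.05) and the membrane protein MALL (-1.68 ± 0.26, -1.60 ± 0.37 and -1.85 ± 0.05). Among the pairs of lines in the edgeR tests, the strongest departure from independence was between C4-2B and 22Rv1. There, 1597 genes fell in the first and rose in the second against 1262.3 for independent lists, and 851 fell in both against 1003.9. Between 22Rv1 and DU145, 1668 genes rose in both against 1548.3 and 1319 fell in both against 1179.6. In opposite directions, 1507 rose in 22Rv1 and fell in DU145 against 1483.1, and 1180 did the reverse against 1231.4. With limma-voom on the same genes, 283 rises and 309 falls were shared by all 3 lines, against 329.2 and 294.6. DESeq2 gave 208 rises and 260 falls, against 142.6 and 175.6. Its set of 18275 genes had no filter on low counts and kept any gene left without an adjusted p. Genes with too few reads to pass lower the number that independent lists would share. The DESeq2 excess over that number therefore cannot be set against the edgeR and limma-voom counts.

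Tested directly, the fold changes of 9620 genes differed between C4-2B and 22Rv1, of 7845 between C4-2B and DU145 and of 9540 between 22Rv1 and DU145. The lamin B1 gene LMNB1 was 1 of them. Its fold change in C4-2B less that in 22Rv1 was -1.83 ± 0.07 (adjusted p = 3.45e-20), and less that in DU145 it was -1.60 ± 0.07 (adjusted p = 1.89e-18). KRT8 in DU145 lay below both others (C4-2B less DU145 1.58 ± 0.06, 22Rv1 less DU145 0.89 ± 0.06), and so did FLNA (1.40 ± 0.07 and 0.72 ± 0.07). Of the lists, G1/S and G2/M differed in every pair, and p53 targets differed between C4-2B and each other line. Between 22Rv1 and DU145 the calls of G1/S and G2/M were lost (adjusted p = 0.207 with an estimated correlation, for both). Line, batch label and table coincide, so these differences cannot be assigned to the line alone.

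**Figure D3:**
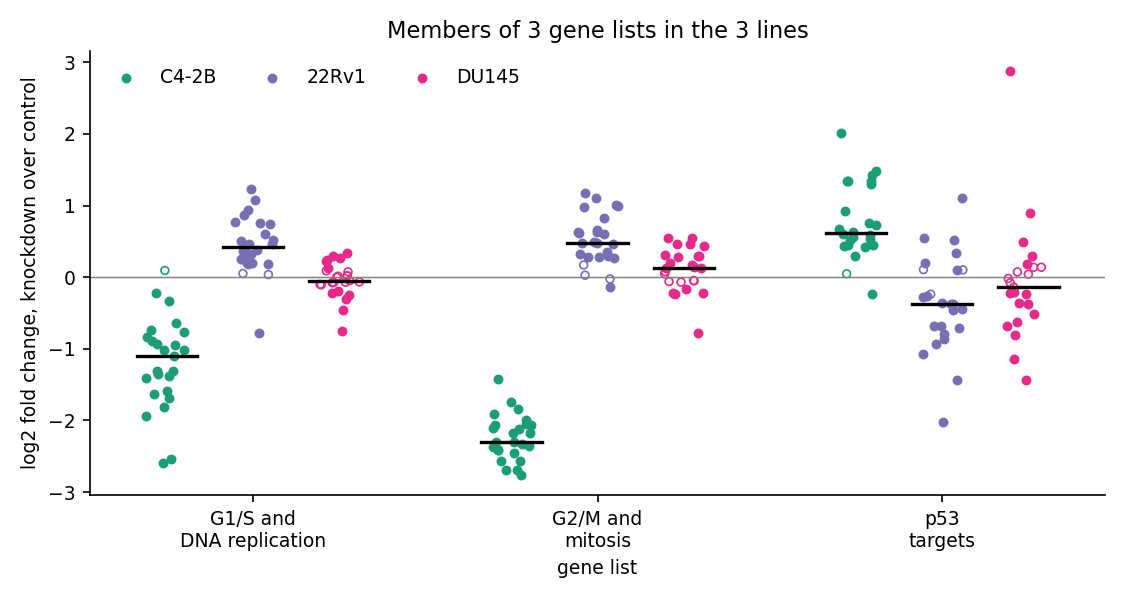
Log2 fold change, knockdown over control, of each tested member of 3 gene lists in C4-2B (green), 22Rv1 (purple) and DU145 (pink); filled points have an adjusted p under 0.05, open points do not, and black lines are medians. The medians of G2/M and mitosis are -2.30, 0.47 and 0.13, and those of p53 targets 0.62, -0.37 and -0.14.

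**Figure D4:**
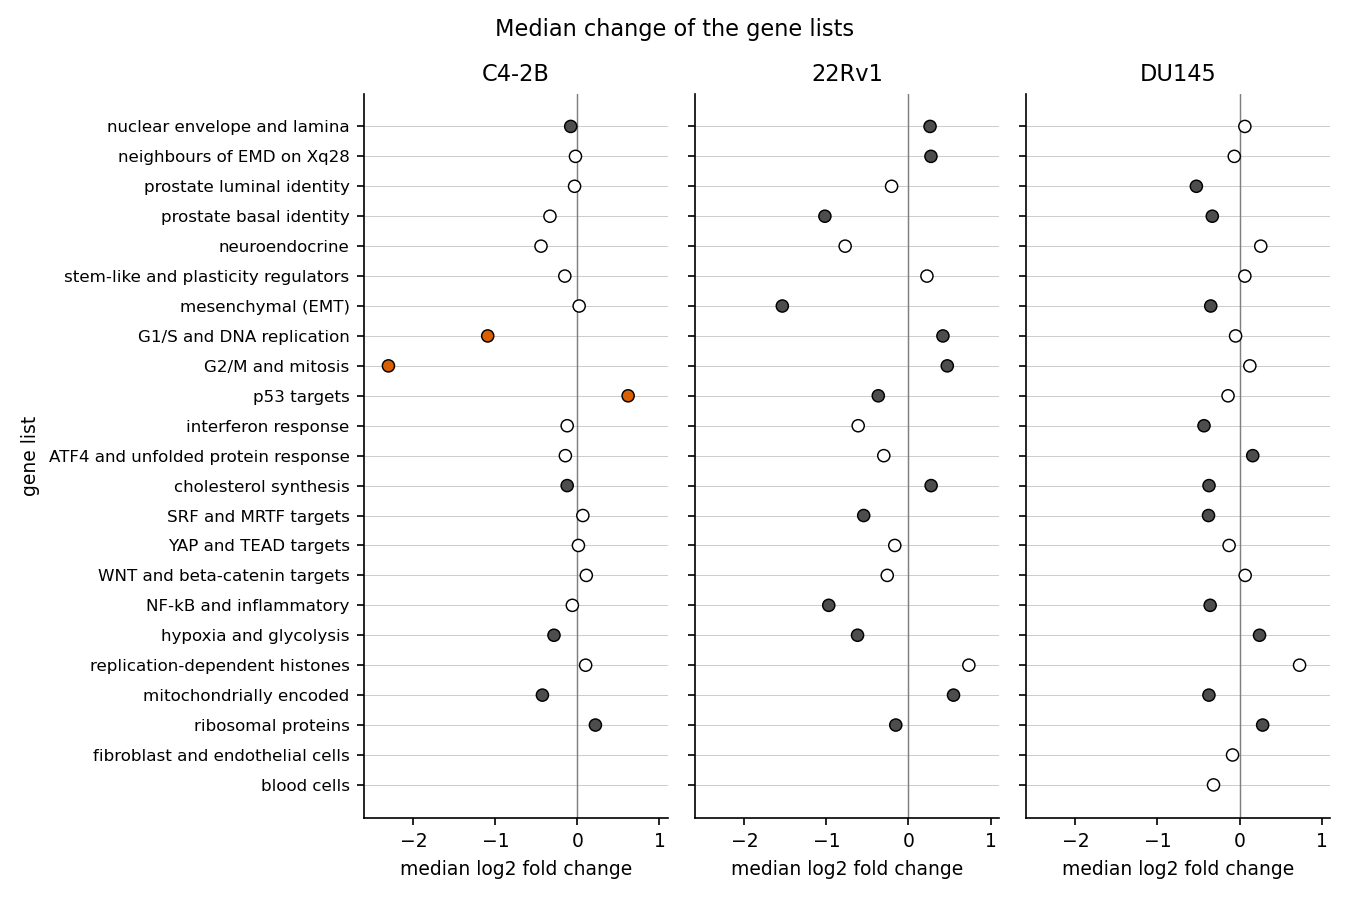
Median log2 fold change of the members of each gene list shown, per line, for lists with at least 5 tested members. Orange points pass the threshold of 0.05 with the preset and with an estimated correlation (3 of those shown, in C4-2B), grey points with the preset correlation only and white points with neither.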

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

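The tests of whether regional shifts run over neighbouring windows, of evenly spread genomic DNA and of other splits of the libraries were chosen only after the results were seen, and the noise test on genes at 10 CPM or more was added once the test on all genes had left the question undecided.

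The response to EMD knockdown differed between the lines by a test of the difference itself, for 9620 genes between C4-2B and 22Rv1, 7845 between C4-2B and DU145 and 9540 between 22Rv1 and DU145. Of 249 named genes tested, some of them named for the size of their difference or change, 206, 177 and 209 differed. The fold change of EMD itself differed by -1.29 between C4-2B and 22Rv1 and by 1.42 between 22Rv1 and DU145. The number of genes changed within a line was 6584 in C4-2B, 11288 in 22Rv1 and 9232 in DU145, and in each line only 1 of the 10 splits of the 6 libraries, the real one, gave as many. The highest of the other splits gave 0 genes in edgeR, with between 140 and 262 genes at an unadjusted p under 0.05 in C4-2B, 33 to 84 in 22Rv1 and 89 to 645 in DU145. With 10 splits no share under 0.05 can be reached. Each other split also puts control and knockdown libraries into the same group, which widens the spread and pushes its count towards 0. The splits therefore cannot decide whether the counts arose by chance.

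Of 23 lists, 9 differed between C4-2B and 22Rv1: G2/M and mitosis (camera adjusted p = 2.27e-25), G1/S and DNA replication (7.52e-18), ribosomal proteins (3.85e-13), p53 targets (1.25e-12), mitochondrially encoded (8.71e-07), cholesterol synthesis (0.000293), nuclear envelope and lamina (0.00182), mesenchymal (0.0206) and NF-kB (0.0301). Between C4-2B and DU145, 7 differed: G2/M and mitosis (2.21e-28), G1/S and DNA replication (1.61e-16), p53 targets (8.15e-10), hypoxia and glycolysis (4.04e-05), ATF4 and unfolded protein response (0.0146), SRF and MRTF targets (0.027) and 1 list not reported by name (0.0094). Between 22Rv1 and DU145, 7 differed: ribosomal proteins (1.41e-13), hypoxia and glycolysis (6.13e-08), mitochondrially encoded (3.46e-07), cholesterol synthesis (1.22e-06), G1/S and DNA replication (1.53e-06), G2/M and mitosis (9.76e-05) and nuclear envelope and lamina (0.0156). With an estimated correlation, 3 of the first 9 passed, G2/M (adjusted p = 0.0026), G1/S (0.0143) and p53 (0.0015). Of the next 7, 4 passed, G2/M and p53 (0.00319 each), G1/S (0.0194) and the unnamed list (0.0245). Of the last 7, 0 passed. The nuclear envelope list of these comparisons includes EMD itself.

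The genes with the widest gaps between C4-2B and 22Rv1 were SCN4B (9.05, first line less second, log2), HSPA6 (8.03), LARP6 (7.44), C1RL (7.00) and MRC2 (6.77). Between C4-2B and DU145 they were BCHE (17.02), SPOCD1 (9.39), ENSG00000285816 (8.89), CACNA2D1 (-8.84) and ENSG00000262633 (-8.83). Between 22Rv1 and DU145 they were BCHE (14.04), SCN4B (-9.75), UCA1 (-9.61), LYNX1 (-8.44) and NUDT11 (-8.26). Where a gene has few or no reads in an arm, as BCHE in the DU145 knockdown and SCN4B in the 22Rv1 knockdown, the size of the gap depends on the prior count. MRC2, SPOCD1 and ENSG00000285816 were not tested within C4-2B, UCA1 and NUDT11 not within 22Rv1, and SCN4B not within DU145. The SE of the gap was 2.87 for ENSG00000285816 and 2.92 for ENSG00000262633. ENSG00000262633 did not pass within C4-2B (edgeR adjusted p = 0.0898) or DU145 (0.221).

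The fold changes of the 3 lines were almost uncorrelated across genes. Genes of low count do not hide a shared response, since the highest absolute correlation among 7721 protein-coding genes at 10 CPM or more was 0.051, and neither do trends with GC content and length, after whose removal it was 0.067. Noise between the libraries of a line is argued against for well-expressed genes, where 2 disjoint estimates of the same line correlated at 0.851 or more. It was left undecided for all genes (0.608 or more, against a bound of 0.7). Noise between cultures was not tested, as the labels do not say whether the triplicates were separate cultures. A biological difference between the lines stays open as a hypothesis, untested. It cannot be told apart from the batch label, the table and, for DU145, the medium and the reagent, and in the pairs with 22Rv1 from the depth of the knockdown, which did not differ detectably between C4-2B and DU145.

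In DU145, 13 windows of 20 Mb shifted as a whole, and 13 genes of DU145 and 18 of 22Rv1 switched between 5 CPM or more and almost no reads. Sampling does not account for these genes, the least covered of which held 390 reads in its higher arm. A copy number difference between control and knockdown cultures was tested by the highest absolute window median, 0.383 in 22Rv1, between the bounds set for it, and 0.623 in DU145, which met the bound set for such a difference. The nearest expressed neighbours of the switching genes moved by a median of 0.113 in 22Rv1 (17 of the 18 genes) and 0.138 in DU145, which argues against lost or gained stretches as the source of the switches as a set, a verdict reached with the DU145 value already known; it stays open for the 6 genes of 22Rv1 and 4 of DU145 whose neighbours moved with them by the bound of 0.3 or more, up to 1.18 beside PRSS56 and 1.90 beside IL24. For the regional shifts themselves, a loss of 1 copy in 3 or a gain of 1 copy to 2 (log2 ratios -0.585 and 0.585) remains a possible explanation, and no DNA was measured. Of 11 further windows beyond 0.3, 5 adjoin a shifted window of the same sign, short of the bound of over 0.5 of them. In general 10 of 141 windows adjoin one of either sign. The count takes only neighbours of the 13 shifted windows and leaves out runs among those 13. It also leaves out adjoining windows from 0 to 40 Mb on chromosome 5 (-0.337 and -0.441) and from 40 to 80 Mb on chromosome 20 (-0.367 and -0.464). On chromosome 15 all windows from 20 to 100 Mb were lower (-0.521, -0.394, -0.346 and -0.3). Windows from 60 to 160 Mb were all lower on chromosome 7 (-0.584, -0.411, -0.407, -0.486 and -0.592). Over the same span of chromosome 8 they were all higher (0.55, 0.557, 0.508, 0.428 and 0.38). Beside the shifted window of chromosome 11 the median was -0.218. The count sees only part of such runs, so missing its bound does not argue against contiguous segments.

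In 22Rv1, genes of low expression fell together, with medians of -0.44 at 0.5 to 2 CPM and -0.33 at 2 to 10 CPM. A GC content bias does not account for it, since the median over both classes was -0.39 once GC and length trends were removed, nor does depth, since it was -0.386 in libraries thinned to 15602874 reads. Genomic DNA spread evenly over the control libraries is argued against by the 10.2% of long genes that lie below 0.1 of the level it needs. Background reads in general, unspliced RNA included, stay open. Among the listed long genes 441 held 3 or fewer control reads, between the 2 bounds set for that test. Genes of few reads were already absent from the 22Rv1 table, where the lowest total of a gene was 2. That can only lower the count of 441, so the upper bound may have been missed for this reason and the test cannot decide. No biological explanation was tested.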

How the results depend on the processing

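The correction for regional shifts was chosen only after the data were seen. EMD kept its direction and passed the threshold under all 15 settings in each line (log2 fold change -3.24 to -2.91 in C4-2B, -1.82 to -1.67 in 22Rv1 and -3.24 to -3.15 in DU145). Requiring at least 2-fold left 1047 of the genes changed in C4-2B, 3065 of the genes changed in 22Rv1 and 1592 of the genes changed in DU145, fewer by construction. An estimated correlation left 4, 0 and 0 lists, with 4, 5 and 2 at an unadjusted p under 0.05 in camera, while fry, which does not compare a list with other genes, passed 19, 22 and 18; beyond these constructions the cause was not tested. Leaving out 1 library gave 5620 to 6258, 10661 to 11016 and 8213 to 9525 genes, 8 to 9, 14 to 16 and 11 to 14 lists, and 479 to 622 shared genes. For the differences between lines it gave 9153 to 9464, 7323 to 7666 and 9007 to 9304 genes. Same-numbered libraries did not clearly pair. The correlations of their deviations ran from -0.04 to 0.294, and not every library correlated best with its own number. In DU145 the same-number values were 0.128, 0.294 and 0.035, against -0.233 to 0.141 for other numbers, so pairing there stays undecided. With a replicate block 6623, 11146 and 9860 genes and 8, 14 and 9 lists passed; the calls that ended were nuclear envelope in C4-2B (adjusted p = 0.0528) and luminal identity and NF-kB in DU145 (0.0516 each). Of 397 named genes 19 changed their side of the threshold under some setting, as did 55 of 68 lists, and 0 of either reversed while past it. By setting, the estimated correlation moved 30 lists below the threshold, fry 25 above, the replicate block 3 below, library totals 1 each way, and the window correction 3 below and 4 above. Alternatives for normalized values did not apply. Depth sets the floor for a gene without reads, 3 reads over the knockdown arm being 0.061 CPM in C4-2B, 0.0517 in 22Rv1 and 0.0298 in DU145.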

Other observations

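The gene families below were grouped by symbol and tested only after the data were seen, as was the correction for regional shifts.

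Nuclear pore genes moved in opposite directions in 2 lines. In C4-2B 14 of 22 tested NUP genes fell and 0 rose (median -0.27, camera adjusted p = 0.000104, and adjusted p = 0.6 with an estimated correlation), while in 22Rv1 17 rose and 2 fell (median 0.28, adjusted p = 0.0046, and adjusted p = 0.409 with an estimated correlation). Genes of the mitochondrial ribosome's large subunit (MRPL) fell in 26 of 49 cases in C4-2B (median -0.18, adjusted p = 9.88e-05, and adjusted p = 0.728 with an estimated correlation). They rose in 33 of 49 cases in 22Rv1 (adjusted p = 0.00346, and adjusted p = 0.597 with an estimated correlation) and in 37 of 49 in DU145 (median 0.26, adjusted p = 5.05e-07, and adjusted p = 0.972 with an estimated correlation). In 22Rv1, where genes of low expression fell together (medians of -0.44 at 0.5 to 2 CPM and -0.33 at 2 to 10 CPM), collagen genes fell in 18 of 23 cases (median -1.43, adjusted p = 0.00298, and adjusted p = 0.409 with an estimated correlation) and WNT ligand genes in 14 of 17 (median -2.02, adjusted p = 0.006, and adjusted p = 0.409 with an estimated correlation). RNA helicases of the DDX family rose in 27 of 34 cases there (median 0.42, adjusted p = 9.07e-05, and adjusted p = 0.409 with an estimated correlation). Medians over all genes were 0.134 at 30 to 100 CPM and 0.146 from 100 CPM in 22Rv1, which stands beside the rises of its NUP, MRPL and DDX genes. In DU145, tetraspanins fell in 13 of 18 cases (median -0.57, adjusted p = 0.00286, and adjusted p = 0.972 with an estimated correlation).

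Of 83, 87 and 97 families tested in C4-2B, 22Rv1 and DU145, 10, 17 and 7 passed with the preset correlation. With an estimated correlation camera passed 0 in each line, with 5, 8 and 0 at an unadjusted p under 0.05.

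Neighbours of EMD on Xq28 moved apart. FLNA, 4.6 kb away, gave 0.17 ± 0.04 in C4-2B, -0.46 ± 0.04 in 22Rv1 and -1.246 ± 0.053 in DU145. RPL10, 8.4 kb away on the other side, gave 0.50 ± 0.04, -0.11 ± 0.03 and 0.22 ± 0.05, and LAGE3, 96.2 kb away, -0.29 ± 0.07, 1.06 ± 0.06 and 1.18 ± 0.09, with all 9 values past the threshold.

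The 13 shifted windows of DU145 lie on chromosomes 7, 8, 10, 11, 15 and 21. On chromosome 8 the windows from 0 to 40 Mb were lower and those from 60 to 120 Mb higher. With window medians removed, 8443 genes changed in DU145, 7572 of which had changed without the correction, while 1660 were lost and 871 gained.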
